A study of Homo sapiens with 4 samples.

How the data were processed

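miRNAs of K562 cells and of the exosome fraction of their medium were profiled after 24 h at 20% or 1% oxygen, with 1 sample in each of 4 groups. Per the labels' protocols, the medium was filtered before exosomes were precipitated with a commercial reagent, the plant miRNA ath-miR159 was added to each lysate, and RNA was purified by phenol extraction and cartridges. Reverse transcription used a pool of primers and a fixed volume of RNA, per the labels' protocols, so the input was not set by RNA amount. The labels' protocols state a further amplification for the exosome samples and name none for the cells. TaqMan Human miRNA Array A cards were read on a real-time PCR cycler and processed by the authors in Data Assist 3.1, per the series design text.

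The authors' deposited table gives linear fold ratios of one sample over another, per the file headers, in 2 columns of 384 wells. Of these, 377 are human miRNA assays with 1 row each and 7 are control wells. The control behind each column was read from the wells that stand at exactly 1, the 4 U6 wells in one column and the 1 spike well in the other. The series design text names RNU6B as the control for cells, while the U6 wells are called MammU6 in the table. The header names no group for the samples it numbers, so neither the oxygen level nor the compartment of a numbered sample is stated there. Any error of these control wells is carried into every miRNA of the column.

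A second table holds 4 columns of raw cycle thresholds headed by sample numbers, the same numbers as in the ratio headers. No sample label carries those numbers, so the 4 columns were not matched to samples and not used. The design fixed before the data were examined had assumed them. Its filters on late amplification, its bounds for miRNAs measured in 1 sample, its comparison of levels between cells and exosomes and its matching of random lists on expression were therefore not run, and the deposited ratios took the place of its fold changes. Signal and detection behind each ratio were not analysed here, because those columns were left out of every step. If equal numbers mean the same samples, they could be read for the numbered ratios without a match to labels.

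Log2 ratios were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, without a pseudocount. The commonest ratio of each column was taken as uninformative and miRNAs at any other ratio as informative, a rule that was not in the design. A miRNA was counted as higher or lower at 2-fold or beyond, and no p-value was computed because no group has a replicate. The rule for named miRNAs took the 10 largest increases and decreases in each comparison and in their difference, miR-210, and examples from each list. Its limit on cycle thresholds was not applied, and neither was its choice of list examples by lowest threshold. List examples outside the 10 largest were therefore chosen after their values were seen.

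The 21 lists of families, clusters, blood cell and tissue markers were fixed before the data were examined, from general knowledge, and some miRNAs are in several. Where 3 or more members were informative, the list's median was placed among the medians of 10000 random lists of the same size drawn from the informative miRNAs, which describes these samples and is not a test. This gave 13 U6-scaled and 15 spike-scaled percentiles, and among that many some extreme ones would arise for random lists too. In simulated data a list of 8 miRNAs shifted by 1 on the log2 scale lay at or above percentile 95 in 100 of 100 simulations of the U6-scaled comparison (177 miRNAs) and 100 of 100 of the spike-scaled one (240 miRNAs). An unshifted list did so in 5 and 7. Other list sizes, smaller shifts and downward shifts were not simulated. Every list median found was smaller than the simulated shift, the largest being 0.87 on the log2 scale over 4 members. The simulation therefore does not show how well the percentiles pick up the differences seen here. miRNA names are those of the array and can be old, and assays of close relatives can cross-react. For genomic clusters, 317 of 377 miRNAs were matched by name to 1 gene of a RefSeq table on GRCh38.p14, names shared by several gene copies being left out, and neighbours at most 10 kb apart were put in one cluster. The authors' deposited table names no genome build, so no coordinates are given.

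The alternatives tried were other references (the median of the informative miRNAs, the mean of RNU44 and RNU48, and the other control, of which those at the shared ratio of a column give no independent reference there), other limits of size, other sets of miRNAs, and a rank correlation. Plots were drawn with matplotlib 3.10.9.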

Results

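K562, a human line derived from chronic myeloid leukaemia, was grown for 24 h at 20% or 1% oxygen, and miRNAs were measured in the cells and in the exosome fraction precipitated from the medium. The design holds 4 groups of 1 sample each: normoxic cells, hypoxic cells, normoxic exosomes and hypoxic exosomes. The question it poses is which miRNAs differ between low and normal oxygen inside the cells and in the vesicles they release. Values came from TaqMan arrays, on which each miRNA has its own PCR assay. All ratios are those of the authors' deposited table, which holds 384 wells, of which 377 are human miRNA assays, with 2 ratios per well. Its header calls these sample 2 over sample 1 and sample 4 over sample 3 and names no group, so higher and lower refer to the numerator sample and not to hypoxia. In the authors' deposited table the 4 U6 wells stood at exactly 1 in the first ratio, called U6-scaled here, and the plant spike ath-miR159a at exactly 1 in the second, called spike-scaled. The series design text assigns a U6 control, RNU6B, to the cells and the spike to the exosomes. With 1 sample per group there was no replicate error and no test, miRNAs were singled out by size alone, and the signal behind each ratio was not analysed here.

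miR-210, the miRNA best known for its induction by low oxygen, was higher in the numerator sample of both comparisons, at 2.94 U6-scaled and 2.05 spike-scaled in the authors' deposited table. miR-18b, of the cluster on the X chromosome that is paralogous to miR-17~92, was also past 2-fold in both ratios of the authors' deposited table, at 2.07 and 2.39. The only other miRNA past 2-fold upward in both was miR-200a, an epithelial marker, which the authors' deposited table lists at 18115 and 9071. The spike-scaled ratio of miR-210 did not reach 2-fold relative to the median of the informative miRNAs, at 1.87, while its U6-scaled ratio was 2.81 relative to that median and 3.32 relative to RNU44 and RNU48. The U6-scaled ratio of miR-18b fell just short of 2-fold relative to the median, at 1.98.

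Many assays carried no information on a difference. A total of 201 wells of the authors' deposited table had the same U6-scaled ratio of 1.0619, and 143 wells had the same spike-scaled ratio of 1.0796. The next most frequent ratio was held by 4 and 2 wells. Equal raw values in both samples give such a shared ratio after scaling, as would assays that reached a detection ceiling in both. A ceiling would mean that controls at the shared ratio went undetected in both samples, although the spike was added to each lysate. Which of these holds was not checked. The spike stood at the shared ratio in the U6-scaled comparison of the authors' deposited table, and U6, RNU44 and RNU48 did in the spike-scaled one, so these controls give no independent reference there. Apart from these, 177 miRNAs were informative in the U6-scaled and 240 in the spike-scaled comparison. A ratio with only 1 of its samples at a ceiling would be a bound, and the authors' deposited table does not mark such ratios, so extreme values are given as listed.

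In the U6-scaled comparison miR-215, miR-23a and miR-105 were among the miRNAs with the highest ratios, and miR-485-5p and miR-324-5p had the lowest. A total of 18 miRNAs were at least 2-fold higher, 6 were at least 2-fold lower and 153 informative miRNAs lay between. Below miR-200a, the authors' deposited table lists miR-325 at 510.0, miR-215 at 9.61, miR-23a at 4.25, miR-105 at 4.23 and miR-210 at 2.94. Next in the authors' deposited table were miR-125a-3p and miR-433, both at 2.91, miR-148a at 2.87 and miR-501-3p at 2.75. Of the miRNAs named here, miR-325, miR-501-3p and miR-485-5p were at the shared ratio in the spike-scaled comparison. The lowest ratio in the authors' deposited table was that of miR-485-5p at 0.0337, followed by miR-324-5p at 0.243, miR-199a-3p at 0.327, miR-194 at 0.377, miR-548b-5p at 0.426 and miR-340 at 0.490. The ratios of miR-505, miR-375, miR-744 and miR-520e, from 0.517 to 0.574 in the authors' deposited table, did not reach 2-fold as deposited. Relative to the median miRNA miR-505 and miR-375 did, at 0.495 and 0.4997, and relative to RNU44 and RNU48 miR-340 did not, at 0.553. miR-194, a copy of which is encoded beside miR-215, thus stood on the other side of 1 from it. The informative ratios had a median of 1.05 and quartiles of 0.894 and 1.31.

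In the spike-scaled comparison miR-449b, let-7c, miR-377 and miR-99a had the highest ratios after miR-200a, and let-7f and miR-221 had the lowest. At least 2-fold higher were 21 miRNAs, at least 2-fold lower were 8, and 211 informative miRNAs lay between. Relative to the median miRNA, which stood at 1.10 (0.13 on the log2 scale), 16 were higher and 12 lower. The authors' deposited table lists miR-449b at 7.57, let-7c at 3.999, miR-377 at 3.85 and miR-99a at 3.79, and let-7c and miR-99a are encoded together on chromosome 21. Both were among the 13 of the 21 higher miRNAs that were at the shared ratio in the U6-scaled comparison. So were 7 of the 8 lower ones, all but let-7f. Cluster-mates as a whole were no more alike in the spike-scaled comparison than after shuffling (percentile 65.3). In the authors' deposited table miR-618 followed at 2.97, miR-219-5p at 2.95, miR-518f at 2.90, miR-219-1-3p at 2.86 and miR-545 at 2.85. Lowest in the authors' deposited table were let-7f at 0.0159, miR-221 at 0.0671, miR-450a at 0.112, miR-28-3p at 0.131 and miR-199b-5p at 0.155. They were followed in the authors' deposited table by miR-330-5p at 0.272, miR-204 at 0.365 and miR-369-5p at 0.495, while miR-380 at 0.513 and miR-34a at 0.514 reached 2-fold only relative to the median miRNA, both at 0.468. miR-222, which shares a transcript with miR-221, stood at 1.32 in the authors' deposited table. Among miRNAs informative in both comparisons, 8 were at least 2-fold higher and 1 was at least 2-fold lower.

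Of the miRNAs raised by hypoxia in other cell types, 12 of 20 assays were informative in the U6-scaled comparison, where miR-210 and miR-23a were past 2-fold upward and none downward. In the spike-scaled comparison 19 were informative, and miR-210 and miR-181c, the latter at 2.66 in the authors' deposited table, were past 2-fold upward and none downward. The medians of this list were 1.15 and 1.18, at percentiles 82.6 and 83.4 of random lists of the same size. Of the miRNAs tied to blood vessel growth, only miR-210 passed 2-fold as deposited, and relative to the median miRNA it did so in the U6-scaled comparison alone. Their medians were 1.20 and 1.41, at percentiles 81.9 and 96.4, and the endothelial miR-126 stood at 1.15 and 1.08 in the authors' deposited table. The clusters that encode miR-23, miR-27 and miR-24 had a U6-scaled median of 1.83 over 4 informative members, at percentile 98.0. It was 1.75 relative to the median miRNA and 2.07 relative to the mean of RNU44 and RNU48. In that comparison of the authors' deposited table miR-23a stood at 4.25, miR-27b at 2.67, miR-24 at 1.26 and miR-27a at 1.16. miR-27a is encoded beside miR-23a, and miR-23b, encoded beside miR-27b, was at the shared ratio. The median therefore does not show a shift of either cluster as a whole. For the same list the spike-scaled median was 1.33, at percentile 85.7, and no member reached 2-fold.

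The growth-promoting miR-17~92 cluster and its paralogs had medians of 1.09 and 1.15 over 12 informative members in each comparison, at percentiles 65.3 and 68.1. miR-17 stood at 1.11 and 1.04 in the authors' deposited table, and only miR-18b, and in the U6-scaled comparison miR-19a at 2.02, were past 2-fold. Relative to the median miRNA neither reached 2-fold in the U6-scaled comparison, at 1.98 and 1.94. In the authors' deposited table miR-18a stood at 0.984 and 1.17. There the cluster-mates of miR-18b did not move with it, miR-106a being at 1.13 and 1.18 and miR-20b at 1.30 and 1.10. Another mate, miR-363, was at the shared ratio in both comparisons. The erythroid miRNAs, which are abundant in the red cell lineage, all stayed within 2-fold, with medians of 1.24 and 0.987 at percentiles 82.6 and 17.3. Among them the authors' deposited table lists miR-451 at 0.719 and 1.43 and miR-16 at 1.26 and 0.936. The family of miR-130a, miR-130b and miR-454 had 5 informative members within 2-fold in each comparison, a U6-scaled median of 0.817 at percentile 4.46 and a spike-scaled median of 1.51 at percentile 96.1. miR-130b stood at 0.667 and 1.51 and miR-454 at 1.47 and 0.777 in the authors' deposited table. No member of the miR-29 family passed 2-fold; the medians were 0.778 at percentile 7.43 and 1.09 at percentile 45.3, the latter falling to 0.990 relative to the median miRNA. The miR-15 and miR-16 family, with no member past 2-fold, had medians of 1.33 at percentile 86.7 and 1.00 at percentile 19.3.

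Of the let-7 family, which restrains growth in many tissues, 4 of 8 assays were informative in the U6-scaled comparison, where the authors' deposited table lists let-7f highest at 2.17. In the spike-scaled comparison 7 were informative, with let-7c past 2-fold upward and let-7f downward. The medians were 1.31 at percentile 85.4 and 1.08 at percentile 40.3, and the second fell to 0.987 relative to the median miRNA. miR-30b stood at 1.23 and 0.850 and miR-30c at 0.812 and 1.07 in the authors' deposited table. miR-181a was at 1.30 in the spike-scaled comparison of the authors' deposited table and, like miR-181c, at the shared ratio in the U6-scaled one. Of the miRNAs linked to p53, miR-215 was past 2-fold upward and miR-194 downward in the U6-scaled comparison and none was in the spike-scaled one as deposited, where miR-34a was past 2-fold downward relative to the median miRNA; the medians were 0.842 at percentile 10.5 and 1.18 at percentile 68.0.

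**Figure D1:**
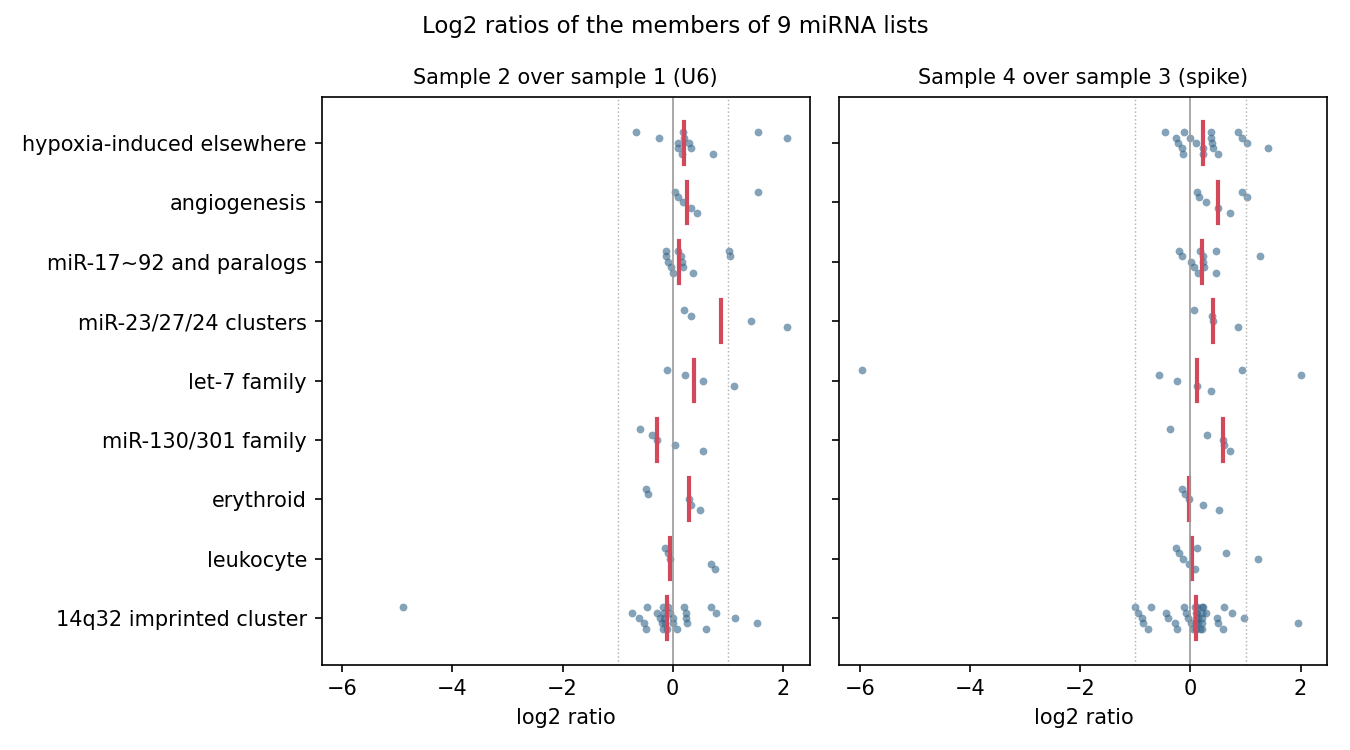
Log2 ratios (x axes) of the informative members of fixed miRNA lists (rows) in the U6-scaled comparison (left) and the spike-scaled comparison (right) of the authors' deposited table; each point is 1 miRNA, the red bar is the list's median and dotted lines mark 2-fold. As plotted no median reaches 2-fold, although that of the miR-23, miR-27 and miR-24 clusters, 1.83 at left, is 1.75 relative to the median miRNA. It is 2.07 relative to the mean of RNU44 and RNU48, 2 wells that differ, at 0.8014 and 0.9795.

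Of all 377 miRNAs, 53.1% were at the shared ratio in the U6-scaled and 36.3% in the spike-scaled comparison. The liver marker miR-122 was at it in both, and so were all 7 muscle and all 7 pluripotency assays in the U6-scaled and 5 of each in the spike-scaled comparison, where the other members stayed within 2-fold. Of 35 assays of the placental cluster on chromosome 19, 33 and 29 were at the shared ratio, and the authors' deposited table lists miR-518b at 2.43 U6-scaled and miR-518f at 2.90 spike-scaled. Leukocyte miRNAs had medians of 0.963 at percentile 24.99 and 1.02 at percentile 18.3, both of which change side of 1 under another reference. Their only member past 2-fold was miR-146a, a regulator of innate signalling, at 1.70 and 2.34 in the authors' deposited table. Among 10 neural assays, of which 6 and 4 were at the shared ratio, the medians were 1.04, or 0.999 relative to the median miRNA, and 1.16, and only miR-219-5p and miR-219-1-3p in the spike-scaled comparison passed 2-fold. Of 7 epithelial markers, of which 5 and 3 were at the shared ratio, miR-200a alone passed 2-fold, and miR-200c stood at 1.09 and 1.29 in the authors' deposited table.

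The imprinted cluster at 14q32 was informative in 29 of 42 assays in the U6-scaled and 39 in the spike-scaled comparison. Its U6-scaled median was 0.936, at percentile 1.43 of random lists, and 1.06 relative to the mean of RNU44 and RNU48. These 2 wells differed, at 0.8014 and 0.9795 in the authors' deposited table, and neither was tried alone. There miR-433 and, at 2.19 in the authors' deposited table, miR-487a were past 2-fold upward, and miR-485-5p downward. Its spike-scaled median was 1.08, at percentile 18.3, and 0.981 relative to the median miRNA, with miR-377 past 2-fold upward and miR-369-5p downward, joined relative to that median by miR-380 and miR-485-3p.

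Setting the comparisons side by side asks whether the same miRNAs differed in both. miR-18b, miR-200a and miR-210 were past 2-fold upward in both as deposited, 3 miRNAs against 1.00 for independent lists among 377, and none was past 2-fold downward in both, against 0.127. Relative to the medians only miR-200a was past 2-fold upward in both, 1 miRNA against 0.679. The values for independent lists include miRNAs at a shared ratio, which could not pass 2-fold there. In the U6-scaled comparison, 13 of the 21 spike-scaled higher miRNAs and 7 of the 8 lower ones were at the shared ratio. Those values are therefore no fair baseline, and a downward overlap was hardly possible. let-7f was the only miRNA past 2-fold in opposite directions. After subtraction of the median difference of 0.07, 13 miRNAs had a spike-scaled log2 ratio above the U6-scaled one by 1 or more and 13 had one below it by 1 or more. The largest positive differences were 2.62 for miR-324-5p, 2.11 for miR-449b, 1.65 for miR-194, 1.64 for miR-505 and 1.53 for miR-199a-3p, and those of miR-381, miR-340, miR-627, miR-548b-5p and miR-130b ran from 1.42 to 1.11. The largest negative differences were -7.16 for let-7f, -3.28 for miR-215, -1.89 for miR-433, -1.73 for miR-105 and -1.70 for miR-196b, and those of miR-27b, miR-19a, miR-23a, miR-125a-3p and miR-148a ran from -1.41 to -1.21. Over the 173 miRNAs informative in both, Pearson's r of the log2 ratios was 0.71 and Spearman's rho 0.0079, and without miR-200a r was -0.0195, so the correlation rests on that assay. These are correlations across miRNAs, which are not independent replicates, and none of the differences has a replicate check.

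**Figure D2:**
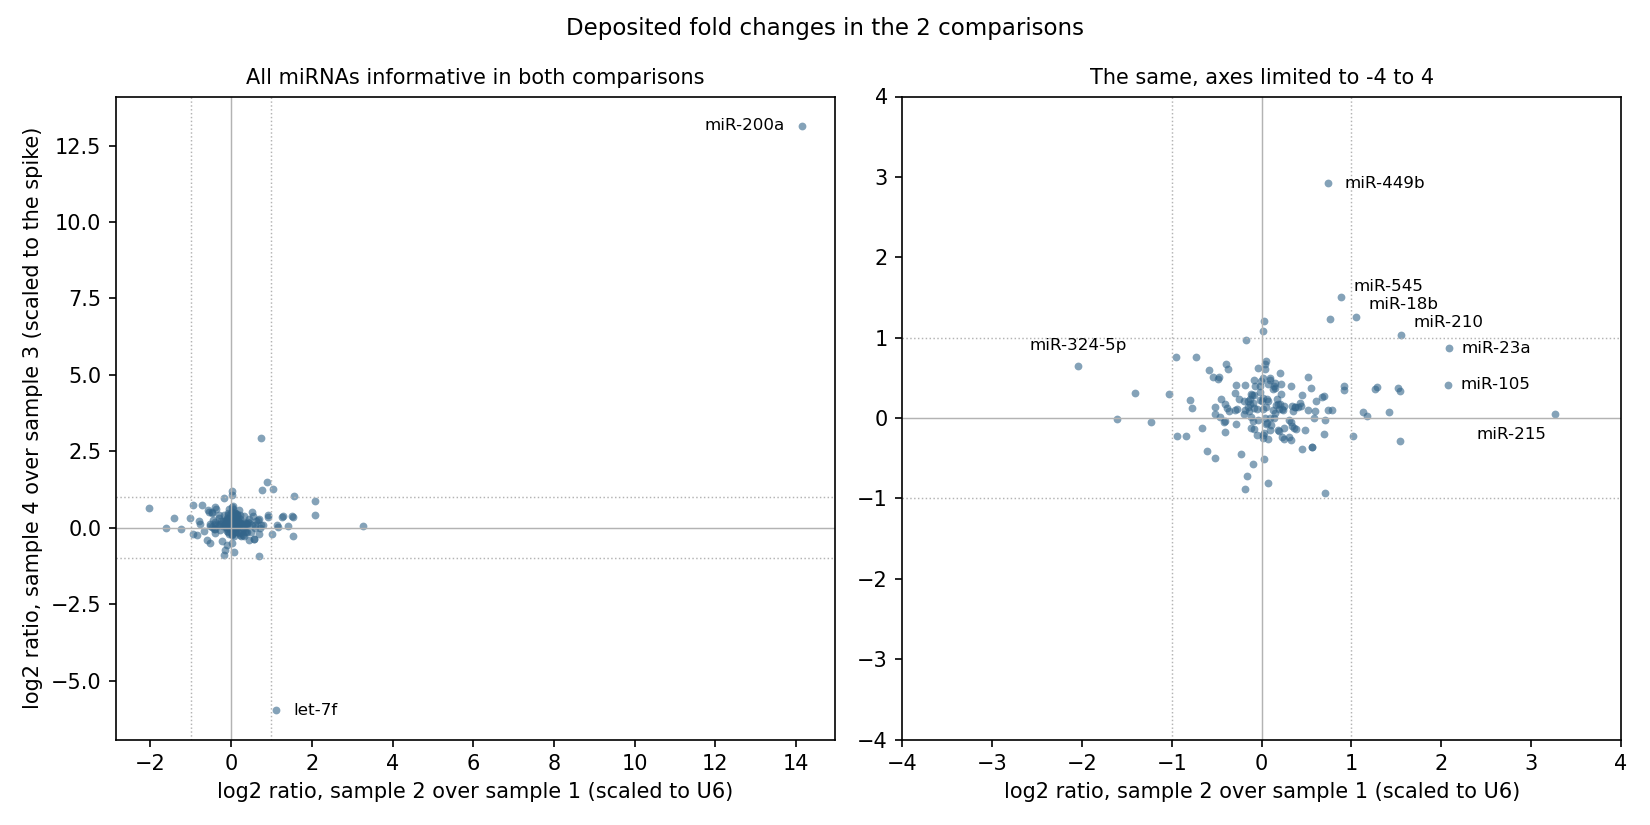
Log2 ratio of sample 4 over sample 3 (y axis, scaled to the spike) against that of sample 2 over sample 1 (x axis, scaled to U6), from the authors' deposited table, for the 173 miRNAs informative in both, over the full range (left) and with axes limited to 4 either side of 0 (right); each point is 1 miRNA and dotted lines mark 2-fold. miR-200a stands apart at upper right, and without it Pearson's r is -0.0195.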

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

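The test in this part was chosen after its result was seen. let-7f drew attention because it was past 2-fold in opposite directions, at 2.17 in the U6-scaled and 0.0159 in the spike-scaled comparison of the authors' deposited table, a log2 difference of -7.10 before any median was subtracted. The difference was not tested, since each comparison has 1 sample a side. A shift of the whole let-7 family is argued against by the 3 other members informative in both comparisons, let-7a, let-7e and let-7g, whose median difference was -0.18 with a median absolute deviation of 0.06. A failed well in sample 4 may account for the value, and so may a change of let-7f alone; neither was tested, and no explanation by oxygen level was tested because the groups of the numbered samples are not stated.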

How the results depend on the processing

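Chosen after seeing the data were the restriction to miRNAs informative in both comparisons, the use of all 377 miRNAs and the correlation without miR-200a. The rule that takes the commonest ratio as uninformative was not in the design fixed before the data were examined. The median of the informative miRNAs rests on that rule. No paired analysis was possible because each group had 1 sample, and no sample could be left out. Relative to the median of the informative miRNAs (log2 shift 0.06) the U6-scaled comparison had 16 higher and 8 lower miRNAs, against 18 and 6 as reported. Relative to the mean of RNU44 and RNU48 (-0.17) it had 21 and 5. In the authors' deposited table these 2 wells differed, RNU44 at 0.8014 and RNU48 at 0.9795. Neither was tried alone, so values relative to their mean depend much on the RNU44 well. The spike-scaled comparison had 16 and 12 relative to its median (0.13), against 21 and 8 as reported. The spike in the U6-scaled comparison, and U6, RNU44 and RNU48 in the spike-scaled one, stood at the shared ratio, so scaling to them only divides by that ratio and says nothing about stability; only 1 other reference was thus left for the spike-scaled comparison. Under the references away from the shared ratio 99 values of named miRNAs and list medians lay within 1.5 times of those reported, as a single factor per comparison fixes, but 3 of 13 U6-scaled and 4 of 15 spike-scaled list medians changed side of 1 under at least 1 of them. Relative to the medians 1 miRNA, miR-200a, was past 2-fold upward in both comparisons (3 as reported). At 1.5-fold the U6-scaled counts were 32 and 14 and the spike-scaled ones 44 and 17, and at 4-fold 5 and 2, and 2 and 5. Among miRNAs informative in both comparisons the spike-scaled counts were 8 and 1. The 13 positive and 13 negative differences between comparisons became 2 and 2 at a log2 difference of 2, and 26 and 24 with all miRNAs. The correlation of 0.71 was 0.0079 by rank, 0.52 with all miRNAs and -0.0195 without miR-200a. Alternatives that need cycle thresholds (filters on late amplification, values for undetected assays, correlations of levels) were not run, and the signal behind each ratio was not analysed here.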

Other observations

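The tests on miR-200a and the one without the largest genomic cluster were chosen after their results, or those they qualify, were seen. The comparison of hairpin arms and the share of 2-fold ratios at the other comparison's shared ratio were not in the design either.

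Over the pairs of informative arms whose names matched 1 gene, the median absolute log2 difference was 0.96 for 8 pairs in the U6-scaled comparison, against 0.54 after shuffling (percentile 93.3), and 0.43 for 17 pairs in the spike-scaled one, against 0.46 (percentile 43.7). The pairs that follow were picked after their values were seen. In the U6-scaled comparison the authors' deposited table lists miR-485-5p at 0.0337 and miR-485-3p at 0.883, and miR-324-5p at 0.243 and miR-324-3p at 1.10. In the spike-scaled comparison the authors' deposited table lists miR-369-5p at 0.495 and miR-369-3p at 1.96, and miR-330-5p at 0.272 and miR-330-3p at 0.875. Past 2-fold and not yet named were, among others, miR-182 at 2.25 and miR-149 at 2.40 U6-scaled and miR-342-5p at 2.43 and miR-143 at 2.13 spike-scaled in the authors' deposited table, the last at 1.94 relative to the median miRNA.

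miR-200a was listed at 18115 and 9071 in the authors' deposited table, where the next highest ratios were 510.0 and 7.57. For the spike-scaled ratio, signal from the closely related miR-141 is argued against by the log2 ratio of miR-141, -0.21. miR-200b, which shares a transcript with miR-200a and miR-429, stood at a spike-scaled log2 ratio of 0.0068. That value rests on 1 relative, and the series design text assigns the spike to the exosomes, where transcription is not read. It therefore does not decide whether that transcript was induced. The ratios of miR-200b and miR-141 lie below the shared ratio, and miR-429 was at it. If the shared ratio marks equal raw values, the denominator sample had more signal for miR-200b and miR-141. For the U6-scaled ratio induction of that transcript and signal from miR-141 both stay open, because 0 of these 3 relatives were away from the shared ratio. A failed well in both denominator samples also stays open as a candidate explanation, as does a change of miR-200a alone; neither was tested.

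The 2-fold ratios of the spike-scaled comparison lay mostly in miRNAs at the shared ratio of the U6-scaled one: 20 of the 29 miRNAs past 2-fold, or 69.0%, against 47 of the 211 others, or 22.3%. In the other direction only 4 of the 177 miRNAs informative in the U6-scaled comparison were at the spike-scaled shared ratio. These 4 included 2 of the 18 higher miRNAs, miR-325 and miR-501-3p, and 1 of the 6 lower ones, miR-485-5p. No explanation of this was tested.

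A separate hypothesis was that miRNAs of one genomic cluster, which are often transcribed together, have similar ratios. The median absolute log2 difference of cluster-mates was 0.45 over 287 pairs in the U6-scaled comparison, against 0.53 after shuffling (percentile 19.2 of 10000 shuffles). It was 0.50 over 521 pairs in the spike-scaled comparison, against 0.46 (percentile 65.3). Most of these pairs, 230 and 432, lie in 1 cluster, that at 14q32, so the values are largely its own. Without the cluster from miR-379 to miR-410, but with those other 14q32 miRNAs, the median difference was 0.47 over 57 pairs against 0.53 after shuffling (percentile 30.2). In the spike-scaled comparison it was 0.38 over 89 pairs against 0.46 (percentile 21.9). None of these values decides the question.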
